A study of Homo sapiens with 18 samples.

How the data were processed

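Gene expression was measured on Affymetrix 3′ expression arrays in 18 samples of the human melanoma lines A375M2 and C32, in 6 groups of 3 replicates. The deposited values are log2 signals that were made with GCRMA, per the submitters' processing notes; the version of that tool is not given in the sources used here. The table was used as deposited, held 0 missing values, and all of its columns were matched to samples by their labels (0 unmatched). Groups were taken from the labels. The labels do not say which of the GFP vectors in the series description the GFP arrays hold. Selection, culture and sorting are described for A375M2, and for the C32 and NFYA arms these details are not given in the sources used here.

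Of 23416 probe sets, 58 were controls, 20264 had a single gene symbol, 995 had several and 2099 had none or were not listed. Symbols were taken by Entrez gene ID from a reference table for 20254 probe sets. Probe sets were kept at log2 4 or more in at least 3 of 18 arrays, which left out 999, and each gene was represented by its probe set with the highest mean, giving 10940 genes. Control, unannotated and multi-gene probe sets were left out of the gene tests because they name no single gene.

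Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05, and a count at 2-fold or more is given beside it. The planned fit on 18 arrays has 12 residual degrees of freedom; the reported one leaves out C32 GFP replicate 3, which is not an independent array by its values, and has 11. The planned comparisons were A375M2 shFHL2, PMEL and shNFYA and C32 shFHL2, each against the GFP arrays of its line, the lines against each other, and the difference of the shFHL2 effects (interaction). The comparison of A375M2 shFHL2 with shNFYA and its overlap with C32 were added after the data were seen, as were the fits that treat or leave out replicate 3 of A375M2 GFP and PMEL. Of 28 gene lists, 26 had enough measured members and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The planned comparisons and their alternatives, the lists and the rule for named genes were set before the data were examined; the 17-array fit and the added comparison, with its alternatives, were not. Overlaps were set against the counts of independent lists and, where arrays were shared, against 20 simulations of unchanged groups that share a control. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

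Named genes are FHL2, PMEL and NFYA in each comparison; the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap; up to 4 members with the smallest adjusted p in each described list; for each overlap, 5 genes each way with the largest smaller fold; and 5 genes each way in the interaction. Symbols of uncharacterised loci, XIST and Y-linked genes were passed over. RAP1A, the neighbouring genes listed with MINPP1, PAPSS2 and ATAD1, PDIA4, HSP90B1 and CALR in A375M2 shFHL2, and the full membership of the NF-Y list fall outside this rule and were chosen after their values were seen.

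Alternatives were other filters, floors, scalings, probe set choices, variance models, thresholds, array weights, a replicate block and each array left out in turn. The pipeline was tested on simulated data with 50 changed genes of each size among 10940, with the group sizes of the study. At a log2 change of 0.25, 0.5, 1 and 2 it recovered 56, 84, 98 and 100 percent for A375M2 shFHL2 with 9 false calls, 36, 74, 94 and 100 percent for PMEL with 7, and 52, 82, 98 and 100 percent for shNFYA with 7. For C32 shFHL2 it recovered 46, 86, 96 and 100 percent with 12 false calls, between the lines 22, 74, 98 and 100 percent with 10, for the interaction 20, 60, 90 and 98 percent with 6, and for shFHL2 against shNFYA 48, 78, 92 and 100 percent with 6. The array number limits precision: the median SE of a log2 fold change was 0.071 within A375M2, 0.08 in C32 and 0.11 for the interaction.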

Results

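Gene expression was measured in 18 microarrays of total RNA from the human melanoma cell lines A375M2, a metastatic derivative of A375, and C32. The cells had been transduced with lentiviral vectors and fell into 6 groups of 3 arrays. In A375M2 these were a GFP control vector, full-length PMEL, short hairpin RNAs (shRNAs) against FHL2 and shRNAs against NFYA; in C32 they were GFP and the FHL2 shRNAs. FHL2 is a scaffold protein with LIM domains that binds integrins and transcriptional regulators. PMEL is the structural protein of melanosome fibrils, and NFYA is a subunit of the CCAAT-binding factor NF-Y. The comparisons asked what loss of FHL2, gain of PMEL and loss of NFYA did to the transcriptome. They also asked whether C32 responded to the FHL2 shRNAs as A375M2 did.

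The table held 23416 probe sets with log2 values from 0.53 to 16.72, and 10940 genes entered the tests. For A375M2 the series describes arrays from 3 separate experiments; for C32 the labels do not say whether cultures were separate, so p-values there measure only the spread between arrays. In C32 GFP, replicate 3 lay on the mean of replicates 1 and 2 with an SD of 0.00746 over 16823 probe sets, against 0.108 to 0.171 for every other array and its group. It was therefore left out, and C32 GFP values are means of 2 arrays. The arrays also fell into sets by their lowest values. At 186 probe sets where arrays of a set shared an exact low value, the A375M2 shRNA arms lay -0.57 log2 (SD 0.955) from replicates 1 and 2 of A375M2 GFP and PMEL, with 0 equal values. At 26 such probe sets the A375M2 shRNA arms equalled the C32 arms exactly, and at 172 replicates 1 and 2 of A375M2 GFP and PMEL lay 0.00416 log2 (SD 0.00657) from the C32 arms, with 0 equal values. Replicate 3 of A375M2 GFP shared 538 equal values with replicate 3 of A375M2 PMEL and 222 with replicate 3 of C32 GFP. By these low values, the comparisons of A375M2 shRNA arms with A375M2 GFP cross array sets. Those of C32 shFHL2 with GFP, A375M2 PMEL with GFP, and A375M2 shFHL2 with shNFYA do not. Shared low values do not show that the arrays of a set were prepared together. In C32, poly-A spike-in probe sets read 9.37 in GFP and 5.96 in shFHL2. In A375M2, 18S probe sets read 12.52 in GFP and 11.08 in PMEL.

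FHL2 fell by 4.04 on the log2 scale in A375M2 shFHL2, from 11.21 ± 0.05 in GFP to 7.17 ± 0.14 (SD, n = 3; SE 0.144, limma adjusted p = 1.62e-14), a 16.4-fold difference. In C32 it fell by 5.24, from 11.08 ± 0.06 (SD, n = 2) to 5.83 ± 0.46 (SD, n = 3; SE 0.161, limma adjusted p = 2.45e-14), which is 37.8-fold. FHL2 stood at 11.01 ± 0.06 in A375M2 PMEL and 11.10 ± 0.03 in shNFYA, differences of -0.20 and -0.11 that did not pass the test (adjusted p = 0.293 and 0.48). PMEL rose 10.4-fold in the arrays labelled PMEL, from 5.57 ± 0.20 to 8.95 ± 0.06 (log2, SD, n = 3; SE 0.126, limma adjusted p = 1.59e-12). PMEL also fell in A375M2 shFHL2 (-2.22), in A375M2 shNFYA (-2.32) and in C32 shFHL2 (-3.54). Its levels in the A375M2 shFHL2 and shNFYA arms, 3.35 and 3.25, were under log2 4, so these falls may be limited by the lowest values. NFYA fell by 2.07 in A375M2 shNFYA (SE 0.0941, limma adjusted p = 4.33e-13) and fell by 0.73 in A375M2 shFHL2 (limma adjusted p = 1.04e-06). Its difference of -0.12 in C32 shFHL2 did not pass the test (adjusted p = 0.336). All 4 NFYA probe sets were lower in shNFYA than in GFP, from -0.96 to -3.47 log2.

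**Figure D1:**
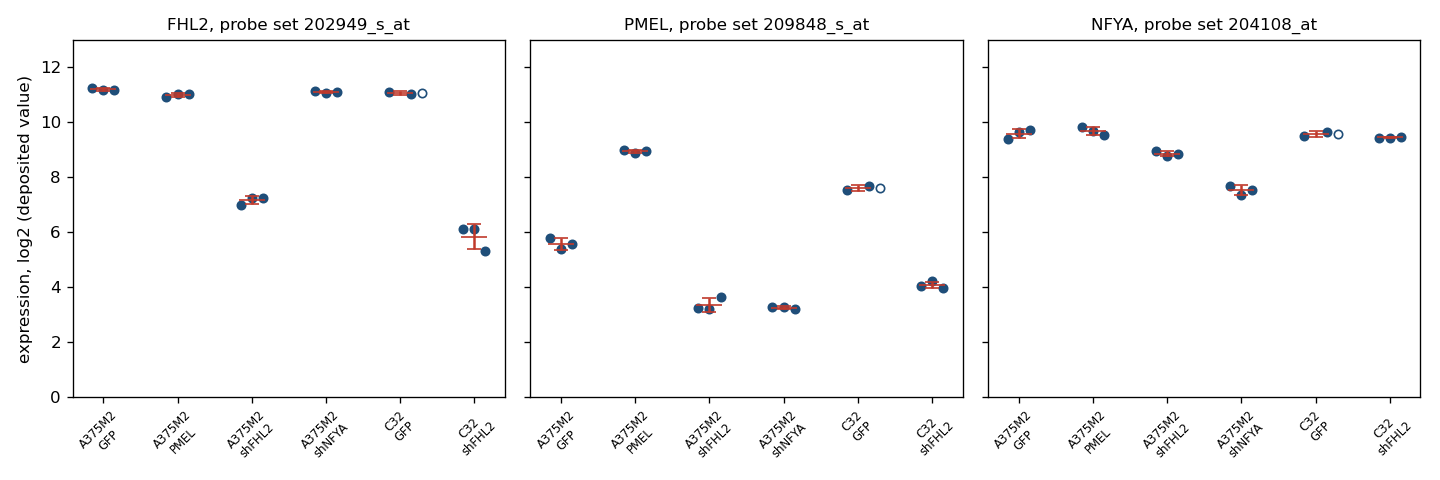
Deposited log2 values of FHL2, PMEL and NFYA in each array (points) of the 6 groups, with the group mean and SD (bars). The open circle is C32 GFP replicate 3, which is left out of mean and SD; FHL2 sits at 7.17 in A375M2 shFHL2 and at 5.83 in C32 shFHL2, against 11.21 and 11.08 in the GFP groups.

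In A375M2, the FHL2 shRNA arrays differed from GFP at most of the genes tested, with pigment-cell genes lower and inflammatory cytokines higher. HGF, the ligand of the receptor MET, fell by 10.46 log2 (SE 0.082, limma adjusted p = 3.23e-23), from 12.71 ± 0.14 to 2.24 (n = 3). SOX9, a neural crest transcription factor, fell by 9.48 from 11.91 ± 0.09. COL6A3, a chain of collagen VI, rose by 9.07 log2 (SE 0.0762, limma adjusted p = 8.05e-23), from 2.22 ± 0.01 to 11.29 ± 0.02. MMP1, the interstitial collagenase, rose by 8.83 from 3.32 ± 0.11.

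For each of the largest rises and falls named here and in the other comparisons, every array of the one group lay above every array of the other, which 10% of genes do by chance with 3 arrays against 3 and 20% with 3 against the 2 of C32 GFP. Of 10940 genes, 9341 passed the test, 4497 higher and 4844 lower (4943 and 4413 with each array centred on its median), and 3431 of these differed at least 2-fold, 1660 higher and 1771 lower. Among the 8 largest rises were also LCN2 at 8.94, CNTN4 at 8.90, CHMP4C at 8.84, SERPINH1 at 8.70, CDH12 at 8.39 and TRHDE at 8.32 log2. SERPINH1 encodes a collagen chaperone, and CHMP4C a subunit of the membrane-scission complex ESCRT-III. The 8 largest falls included MGP at -9.40, ADCY1 at -9.28, ARMCX2 at -8.95, SPATS1 at -8.79, PPP1R3C at -8.78 and GPM6B at -8.22. Most of these genes were near the lowest values of the arrays on one side, so their fold is sensitive to that floor; with values under log2 4 set to 4, HGF was -8.71 and COL6A3 7.29.

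Of 18 measured genes of pigmentation and melanocyte differentiation, 17 fell and 1 rose in A375M2 shFHL2, and the list was called lower (camera adjusted p = 0.000135). MITF, the transcription factor of the melanocyte lineage, fell by 4.18 log2 (SE 0.0527, limma adjusted p = 1.15e-20), and GPNMB, a glycoprotein of melanosomes and lysosomes, fell by 4.16. GPR143, a melanosomal receptor, changed by -6.00, and ST3GAL6 fell by 3.21 although its probe sets disagreed in direction. GPR143 was at -6.00 also in A375M2 shNFYA and in C32 GFP against A375M2 GFP, so its size may be limited by the lowest values. Of 31 genes of G2/M and mitosis, 28 fell and 1 rose (camera adjusted p = 0.000135): TPX2 (-1.82), NUSAP1 (-1.58), CCNB1 (-1.29) and AURKA (-1.21) were among them. Of 17 NF-kB targets and inflammatory cytokines, 14 rose and 1 fell (camera adjusted p = 0.000612). IL1A rose by 7.83 log2, IL11 by 7.78, the prostaglandin synthase PTGS2 by 5.66 and IL1B by 3.56. These 3 lists were also called with an estimated correlation. In this and the other comparisons, called lists given without a second p-value were called either way. In no called list did median, mean and test differ in sign.

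Of 20 genes of the unfolded protein response, 14 rose and 6 fell in A375M2 shFHL2 (camera adjusted p = 0.0155; adjusted p = 0.0591 with an estimated correlation). The members with the smallest p were ASNS at 3.82, TRIB3 at 2.45, ATF4 at 1.93 and HERPUD1 at 1.60 log2; ASNS makes asparagine and is a target of ATF4. The chaperones and folding enzymes of the endoplasmic reticulum PDIA4 (-1.26), HSP90B1 (-0.63) and CALR (-0.61) were among the 6 that fell. Of 25 genes of lysosome and melanosome biogenesis, 20 fell and 3 rose (camera adjusted p = 0.0135; adjusted p = 0.259 with an estimated correlation). Among them were LYST (-3.35), the protease CTSB (-1.84), BACE2 (-1.63) and GUSB (-1.12). Of 25 genes of G1/S and DNA replication, 17 rose and 6 fell (camera adjusted p = 0.0405; adjusted p = 0.396 with an estimated correlation). The replication licensing factors CDT1 and CDC6 rose by 2.35 and 2.12, UHRF1 rose by 1.56, and thymidylate synthase TYMS fell by 1.48. Each of the 6 called lists, adjusted over the list alone, had the same counts of members higher and lower. Markers of keratinocytes and epithelia were higher at 4 of 4 measured genes (median 1.32 log2, camera adjusted p = 0.0654), and 18S ribosomal probe sets read 14.18 ± 0.07 in shFHL2 against 12.52 ± 0.04 in GFP (SD, n = 3). Fibroblast markers were lower at 4 of 5 genes (median -1.48, camera adjusted p = 0.175), and actin probe sets differed from 3′ to 5′ end by 1.07 ± 0.08 in shFHL2 and 0.61 ± 0.13 in GFP (log2, SD, n = 3). Because the arms lie in different array sets, the group and the set cannot be told apart in this comparison.

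Transduction of PMEL into A375M2 moved few genes by a large amount. UTS2, which encodes the vasoactive peptide urotensin 2, rose by 4.69 log2 (SE 0.0829, limma adjusted p = 1.38e-16), from 9.21 ± 0.11 to 13.90 ± 0.08 (SD, n = 3), more than PMEL itself at 3.38. MGST1, a microsomal glutathione transferase, rose by 2.12. ARHGAP20 fell by 4.11 log2 (SE 0.109, limma adjusted p = 2.89e-14), from 6.92 ± 0.09 to 2.81 ± 0.17. Of the gene lists, 5 were called lower, and 0 with an estimated correlation.

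Of 10940 genes, 4365 passed the test, 2419 higher and 1946 lower, but 234 differed at least 2-fold, 57 higher and 177 lower. With each array centred on its median, the balance turned to 2045 higher and 2142 lower. The other large rises were EMX2 at 2.07, LDB2 at 1.87, ABCB4 at 1.86, LY75 at 1.85 and UBAP1L at 1.82 log2; with values under log2 4 set to 4, EMX2 was at 1.09 and UBAP1L at 0.72. The other large falls were CPED1 at -3.89, ZNF385B at -3.87, OLFML3 at -3.27, NPTX1 at -3.12, CNTNAP4 at -3.09, SPATS1 at -2.85 and CSTA at -2.82.

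Of 15 measured YAP and TEAD targets, 10 fell and 2 rose in A375M2 PMEL (camera adjusted p = 0.000202; adjusted p = 0.0603 with an estimated correlation). The ectonucleotidase NT5E fell by 2.14 log2 (SE 0.0575, limma adjusted p = 2.89e-14), and so did the matricellular genes CCN2 (-1.90) and CCN1 (2-fold) and TGFB2 (-1.31). Of 24 integrin and focal adhesion genes, 10 fell and 2 rose (camera adjusted p = 8e-04; adjusted p = 0.0999 with an estimated correlation). ITGA1 (-1.36), ITGB3 (-0.75), ITGA2 (-0.62) and the adaptor PXN (-0.41) fell. Of 19 genes of undifferentiated and invasive melanoma, 10 fell and 1 rose (camera adjusted p = 0.00301; adjusted p = 0.0603 with an estimated correlation). WNT5A (-1.12), TPM1 (-0.87) and CRIM1 (-0.59) fell; CCN1 and CRIM1 are in the YAP list as well. Of 5 measured fibroblast markers, 4 fell (camera adjusted p = 0.000767; adjusted p = 0.0603 with an estimated correlation). Lumican (LUM, -2.03), PDGFRA (-0.55) and FAP (-0.25) fell. COL1A2 fell by 1.01 between levels under log2 4, and the difference was 0 with values under log2 4 set to 4. Of 20 unfolded protein response genes, 11 fell and 2 rose (camera adjusted p = 0.0161; adjusted p = 0.0603 with an estimated correlation).

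The changes of unfolded protein response genes with PMEL were small: PDIA6 fell by 0.40 log2 and HSPA5, the chaperone BiP, fell by 0.18, while ATF3 rose by 0.92. PDIA4 fell by 0.31, a call that was lost when the probe set with the largest variance stood for the gene (-0.14, adjusted p = 0.0705). Adjusted over the list alone, 10 genes were lower and 3 higher in the integrin list, 10 and 2 in the undifferentiated list, and 12 and 2 in the unfolded protein response, while the YAP and fibroblast counts did not move. The pigmentation list, 18 genes including PMEL, was not called (5 rose and 2 fell; camera adjusted p = 0.342). The 18S ribosomal probe sets read 11.08 ± 0.02 in PMEL and 12.52 ± 0.04 in GFP (SD, n = 3).

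The NFYA shRNA arrays of A375M2 differed from GFP as widely as the FHL2 shRNA arrays did, with mitotic and pigment-cell genes lower and inflammatory cytokines higher. FDCSP, a secreted peptide of follicular dendritic cells, rose by 11.16 log2 (SE 0.0929, limma adjusted p = 3.81e-23), from 2.21 to 13.36 ± 0.10 (SD, n = 3). MGP, matrix Gla protein, fell by 10.90 log2 from 13.25 ± 0.11 to 2.35 ± 0.27 (SE 0.143, limma adjusted p = 1.13e-20). FDCSP in GFP and MGP in shNFYA were near the lowest values of the arrays, so their folds are sensitive to that floor. ENPP2, the lysophospholipase autotaxin, fell by 10.04. HGF (-10.46) and SOX9 (-9.75) fell as they had with shFHL2.

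Of 10940 genes, 9501 passed the test in A375M2 shNFYA, 4762 higher and 4739 lower (5261 and 4274 with each array centred on its median), and 3918 of them differed at least 2-fold, 1895 higher and 2023 lower. The further large rises were COL6A3 at 9.16, MMP1 and S100A2 at 9.15, CHMP4C at 9.14, CD24 at 9.12, SCG5 at 9.01 and TRHDE at 8.99 log2. The further large falls were ABCA8 at -9.18, ARMCX2 at -9.07, SPATS1 at -8.79 and PPP1R3C at -8.78. All 31 measured genes of G2/M and mitosis fell (camera adjusted p = 8.87e-08). The kinesin KIF20A fell by 5.12 log2 (SE 0.106, limma adjusted p = 5.09e-18), and NUSAP1 (-2.18), topoisomerase TOP2A (-2.14) and TPX2 (-2.03) fell less. Of 17 NF-kB and cytokine genes, 16 rose (camera adjusted p = 1.31e-05), with IL1A at 8.65, IL11 at 8.31, PTGS2 at 7.90 and IL1B at 6.86. Of 18 pigmentation genes, 16 fell and 1 rose (camera adjusted p = 3.73e-05): MITF (-5.28), GPNMB (-5.40) and GPR143 (-6.00) were among them. As with shFHL2, the size of the GPR143 change may be limited by the lowest values.

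Of 20 genes of the unfolded protein response, 16 rose and 3 fell in A375M2 shNFYA (camera adjusted p = 0.00123), with ASNS at 3.51, TRIB3 at 2.38, HERPUD1 at 1.90 and ATF4 at 1.87. Of 18 genes of MHC class I and II antigen presentation, 15 fell and 2 rose (camera adjusted p = 0.00219; adjusted p = 0.217 with an estimated correlation). HLA-E (-1.44), HLA-DPB1 (-1.37), HLA-DRB1 (-1.36) and HLA-B (-0.97) fell; NF-Y is known to bind MHC class II promoters. The 5 called lists, adjusted over the list alone, had the same counts of members higher and lower. Markers of keratinocytes and epithelia were higher at 4 of 4 measured genes (median 1.76 log2, camera adjusted p = 0.0607), and 18S probe sets read 14.19 ± 0.11 (SD, n = 3). Fibroblast markers were lower at 4 of 5 (median -1.48, camera adjusted p = 0.143), and the actin difference from 3′ to 5′ end was 1.19 ± 0.08 against 0.61 ± 0.13 in GFP (log2, SD, n = 3). As with shFHL2, the group and the array set cannot be told apart.

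In C32, the FHL2 shRNA arrays had higher cell-cycle genes and lower genes of pigmentation, protein folding, interferon response and extracellular matrix. TXNIP, an inhibitor of thioredoxin, rose by 7.98 log2 (SE 0.0669, limma adjusted p = 2.46e-22), from 3.66 ± 0.23 (SD, n = 2) to 11.64 ± 0.02 (SD, n = 3). TLR4, the receptor of lipopolysaccharide, rose by 6.10. IGFBP3, which binds insulin-like growth factors, fell by 8.25 log2 (SE 0.0553, limma adjusted p = 1.16e-23), from 11.48 ± 0.05 to 3.23 ± 0.11. TYRP1, an enzyme of melanin synthesis, fell by 6.62, and TF, transferrin, fell by 5.31.

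Of 10940 genes, 6847 passed the test in C32, 3527 higher and 3320 lower, and 936 of them differed at least 2-fold, 385 higher and 551 lower. The further large rises were SPOCK1 at 4.55, FAM133A and PCSK5 at 4.11, FSTL5 at 4.06, DSEL at 4.05 and IKZF2 at 3.87 log2 (2.20 with values under log2 4 set to 4). The further large falls were LDB3 at -6.88 (-4.58 with that floor), NUPR1 at -5.93, EFEMP2 at -5.87, ZC3HAV1L at -5.76 and FSTL1 at -5.68. Poly-A spike-in probe sets read 9.37 ± 0.28 in C32 GFP (SD, n = 2) and 5.96 ± 0.04 in C32 shFHL2 (SD, n = 3). Hybridisation spike-in probe sets read 12.8 ± 0.13 and 11.87 ± 0.05, and 18S probe sets 13.28 ± 0.13 and 13.94 ± 0.10. The actin difference from 3′ to 5′ end was 1.08 ± 0.02 and 0.87 ± 0.04. Although the C32 arms lie in the same array set, the group and a difference in array preparation cannot be told apart here. Nor can loss of FHL2 be told apart from a difference between the shRNA and GFP vectors, as no group is labelled as a non-targeting shRNA.

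All 31 measured genes of G2/M and mitosis rose in C32 shFHL2 (camera adjusted p = 2.85e-12). AURKA rose 2.3-fold (limma adjusted p = 5.78e-13), UBE2C by 1.08 log2, and CCNB1 and NUSAP1 by 0.95. Of 25 genes of G1/S and DNA replication, 24 rose (camera adjusted p = 4.2e-08), with the ribonucleotide reductase subunits RRM2 and RRM1 at 1.17 and 0.81, MCM4 at 0.88 and TYMS at 0.73. Of 20 unfolded protein response genes, 17 fell and 2 rose (camera adjusted p = 6.45e-08): ASNS (-2.70) fell, as did the endoplasmic reticulum chaperones PDIA4 (-2.30), HSP90B1 (-1.78) and HSPA5 (2-fold). Of 18 pigmentation genes, 14 fell and none rose (camera adjusted p = 2.4e-05), among them ABCB5 (-4.17), RAB38 (-3.62) and PMEL (-3.54).

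Of 22 interferon response genes, 13 fell and none rose in C32 shFHL2 (camera adjusted p = 0.000501), with HERC5 at -4.04, OAS1 at -2.91, IFI6 at -1.79 and ISG20 at -1.73. Of 21 extracellular matrix genes, 12 fell and 2 rose (camera adjusted p = 0.000828): the basement membrane chains COL4A1 (-2.60), COL4A2 (-2.26), LAMA4 (-2.16) and LAMC1 (-0.64) fell. Of 21 hypoxia and glycolysis genes, 14 fell and 3 rose (camera adjusted p = 0.00627), among them ADM (-1.43), ANKRD37 (-1.18) and the glucose transporter SLC2A3 (-0.99). Of 16 receptors and kinases linked to BRAF inhibitor resistance, 10 fell and 1 rose (camera adjusted p = 0.0085): KDR (-2.35), MET (-1.60), IGF1R (-0.77) and STAT3 (-0.52) fell. Of 15 SRF and actin cytoskeleton targets, 11 fell (camera adjusted p = 0.00348; adjusted p = 0.0779 with an estimated correlation), with CCN1 at -1.73, ACTA2 at -1.25 and EGR1 at -1.16. The lysosome list was lower at 15 and higher at 2 of 25 genes (camera adjusted p = 0.0197; adjusted p = 0.177 with an estimated correlation), with CTSB at -1.19. The epithelial-mesenchymal list was lower at 11 and higher at 4 of 20 (camera adjusted p = 0.0477; adjusted p = 0.0779 with an estimated correlation), with TGFB2 at -2.09 and FN1 at -1.12. Adjusted over the list alone, 1 pigmentation gene was higher, and the counts of the other 10 called lists did not move.

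**Figure D2:**
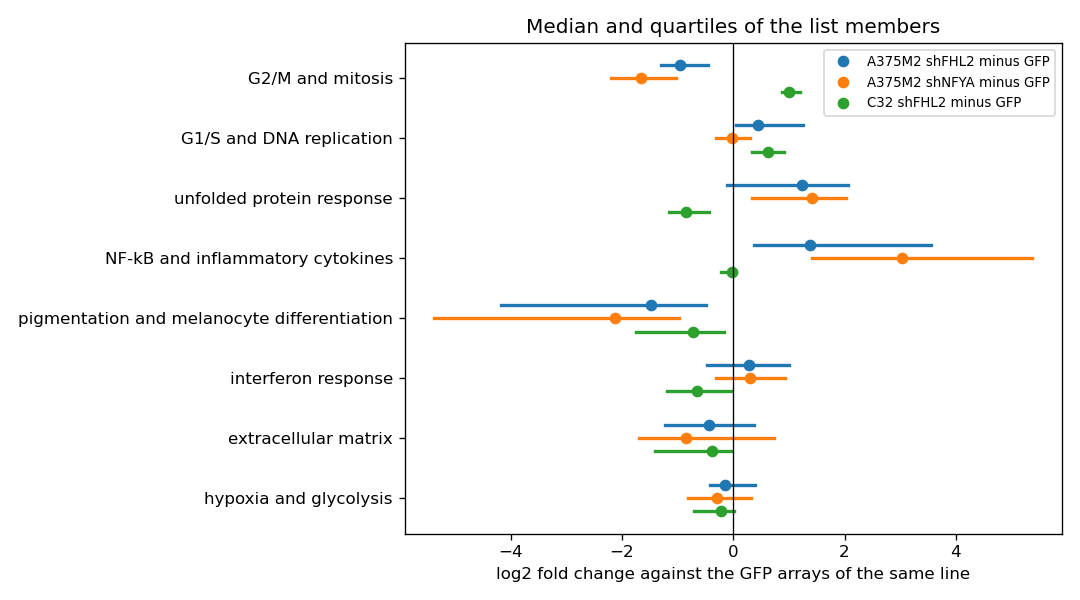
Median (points) and quartiles (lines) of the log2 fold changes of the measured members of 8 gene lists in 3 comparisons with the GFP arrays of the same line. G2/M and mitosis has a median of -0.97 in A375M2 shFHL2, -1.66 in A375M2 shNFYA and 1.01 in C32 shFHL2.

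Without any FHL2 or PMEL vector, the C32 and A375M2 GFP arrays differed in cholesterol synthesis, hypoxia and cancer-testis genes. MLANA, a melanocyte antigen, was higher in C32 by 11.62 log2 (SE 0.0897, limma adjusted p = 7.41e-24), at 14.00 ± 0.03 (SD, n = 2) against 2.38 ± 0.06 (SD, n = 3). TYR, tyrosinase, was higher by 9.05. INHBA, a chain of activin A, was lower by 12.21 log2 in C32 (SE 0.107, limma adjusted p = 3.86e-23), at 2.46 against 14.67. FHL2 stood at 11.08 in C32 and 11.21 in A375M2, a difference that did not pass the test (-0.13, adjusted p = 0.45), and PMEL was higher in C32 by 2.04 log2 (limma adjusted p = 1.54e-10).

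Of 10940 genes, 9394 passed the test between the lines, 4229 higher and 5165 lower in C32, and 4715 of them differed at least 2-fold. The other leading genes higher in C32 were RNASE1 at 10.52, SERPINH1 at 10.30, LHX2 at 9.54, MBP at 9.34, CELF2 at 9.23 and TSPAN7 at 9.18 log2. The other leading genes lower in C32 were MAGEA4 at -11.55, PDK4 at -11.21, TAC1 at -10.95, LINC01419 at -10.83, PAPSS2 at -10.77, TFAP2B at -10.59 and HGF at -10.46. Of 17 cholesterol synthesis genes, 16 were called higher in C32 (camera adjusted p = 1.87e-06), with ACAT2 at 3.95, HMGCS1 at 3.32, MSMO1 at 3.11 and SQLE at 3.10. Of 21 hypoxia and glycolysis genes, 19 were higher and 2 lower (camera adjusted p = 5.34e-06), with NDRG1 at 3.69, PDK1 at 3.11, BNIP3 at 2.66 and P4HA1 at 2.08. G1/S genes were higher at 22 and lower at 1 of 25 (camera adjusted p = 2.27e-06), with CDC6 at 3.52 and CCNE2 at 3.51, and G2/M genes were higher at 22 and lower at 4 of 31 (camera adjusted p = 0.000661), with TTK at 1.99 and ANLN at 1.68. Unfolded protein response genes were higher at 16 and lower at 3 of 20 (camera adjusted p = 0.000353), with PDIA4 at 3.15 and HSPA5 at 1.72.

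Undifferentiated and invasive melanoma genes were lower in C32 at 17 and higher at 1 of 19 (camera adjusted p = 0.00102), with TGFBI at -10.25, THBS1 at -6.73 and WNT5A at -6.38. Cancer-testis antigens were lower at 9 of 11 and higher at 2 (camera adjusted p = 0.0115), with MAGEA1 at -8.17, MAGEC2 at -8.05 and MAGEA6 at -6.27. Pigmentation genes were higher at 12 and lower at 5 of 18 (camera adjusted p = 0.0367; adjusted p = 0.0677 with an estimated correlation), with RAB27A 16-fold higher and GPR143 at -6.00. The size of the GPR143 difference may be limited by the lowest values here too. MHC genes were lower at 16 and higher at 2 of 18 (camera adjusted p = 0.0166; adjusted p = 0.249 with an estimated correlation), with HLA-DMB at -2.47 and CD74 at -1.80. Interferon genes were higher at 15 and lower at 5 of 22 (camera adjusted p = 0.0465; adjusted p = 0.228 with an estimated correlation), with IFIT2 at 3.28 and IFIT3 at 2.92 but MX2 at -8.71. Adjusted over the list alone, 23 G1/S genes were higher, and the other 9 called lists kept their counts. The A375M2 and C32 GFP arrays compared here shared 0 equal values in each pair, although replicate 3 of A375M2 GFP shared 222 with the C32 array that was left out, and a difference between array sets was not separated from that between lines. Poly-A spike-in probe sets read 9.37 ± 0.28 in C32 GFP (SD, n = 2) and 7.15 ± 0.03 in A375M2 GFP (SD, n = 3). In the same order, 18S probe sets read 13.28 ± 0.13 and 12.52 ± 0.04, and the actin difference from 3′ to 5′ end was 1.08 ± 0.02 and 0.61 ± 0.13.

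The effect of the FHL2 shRNAs differed between the lines at 8772 genes by the interaction test, 4604 more positive and 4168 more negative in C32 (4336 and 4441 with each array centred on its median). All 31 G2/M genes were more positive in C32 (camera adjusted p = 2.62e-09), with a median difference of 2.02 log2; NUSAP1 differed by 2.53 (SE 0.063, limma adjusted p = 3.25e-16) and TPX2 by 2.50. All 20 unfolded protein response genes were more negative in C32 (camera adjusted p = 6.67e-09), with ASNS at -6.53, TRIB3 at -3.10, HERPUD1 at -2.70 and ATF4 at -2.40. NF-kB and cytokine genes were more negative at 13 and more positive at 2 of 17 (camera adjusted p = 0.00126), with IL1A at -7.85, IL11 at -7.78, PTGS2 at -5.87 and CXCL8 at -5.35. Interferon genes were more negative at 18 and more positive at 3 of 22 (camera adjusted p = 0.00304; adjusted p = 0.119 with an estimated correlation), with ISG20 at -4.98 and OAS1 at -2.74 but IFITM1 at 3.16. These 4 lists kept their counts adjusted over the list alone. Because the A375M2 arms of this contrast lie in different array sets, the interaction crosses sets as well. Its A375M2 changes were also largely shared with shNFYA (r = 0.896 across genes), where FHL2 was not called different.

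Genes called the same way in both shFHL2 comparisons numbered 3422, 1637 higher and 1785 lower, where independent lists of those sizes would share 1450 and 1470. The balance turned to 1938 higher and 1536 lower with each array centred on its median, and to 1736 and 1688 with quantile normalization. A further 2442 were called in opposite directions. The largest shared rises were in TLR4 (3.89 in A375M2 and 6.10 in C32), CHST7 (2.97 and 2.84), CDYL2 (2.88 and 2.77), MRPS15 (2.66 and 2.44) and NAP1L3 (3.35 and 2.41). The largest shared falls were in TYRP1 (-5.48 and -6.62), TF (-5.75 and -5.31), LXN (-6.91 and -4.78), EDIL3 (-4.63 and -4.76) and ABCB5 (-5.56 and -4.17). With values under log2 4 set to 4, MRPS15 was at 1.45 in A375M2, CDYL2 at 1.24 and NAP1L3 at 0.69 in C32, ABCB5 at -3.56 in A375M2 and EDIL3 at -2.93 in C32. Of the genes at least 2-fold different in both, 93 were higher and 187 lower, against 58.4 and 89.2 for independent lists, and 152 went in opposite directions, against 146. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated with r = 0.126 and rho = 0.146. No group is labelled as a non-targeting shRNA. The shared changes therefore cannot be told apart from a difference between shRNA and GFP vectors that both lines have in common.

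**Figure D3:**
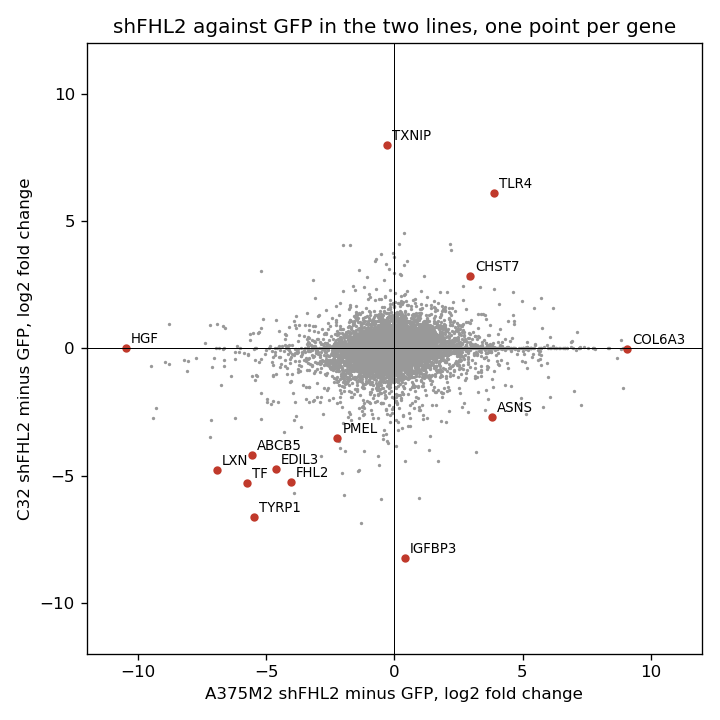
Log2 fold change of shFHL2 against GFP in A375M2 (horizontal axis) and C32 (vertical axis), 1 point per gene, with named genes in red. TLR4 and CHST7 lie in the upper right, TYRP1, TF and LXN in the lower left, and ASNS, at 3.82 in A375M2 and -2.70 in C32, in the lower right.

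The A375M2 shFHL2 and shNFYA comparisons shared 7760 genes called the same way, 3801 higher and 3959 lower, against 1960 and 2100 for independent lists, and 687 were called in opposite directions; with each array centred on its median, 4243 were higher and 3544 lower. Among them COL6A3, CHMP4C, MMP1, SERPINH1 and TRHDE rose and HGF, SOX9, MGP, ARMCX2 and SPATS1 fell by over 8 log2 in both. The fold changes correlated across genes with r = 0.896, and their covariance was 2.05; unchanged groups simulated against the same GFP arrays gave 0.50 and 0.0055. Both comparisons cross the same pair of array sets. PMEL shared 1849 genes with shFHL2, where independent lists would share 994 higher and 862 lower (933 and 916 observed, 880 and 937 with each array centred), and 1986 genes went in opposite directions (1870 for independent lists; r across genes 0.0473, rho -0.0217, covariance 0.0241). It shared 1798 with shNFYA (935 higher and 863 lower, against 1050 and 843), and 2083 went in opposite directions (1890 for independent lists; r 0.0317, rho -0.0537, covariance 0.0181); part of each overlap may come from the shared GFP arrays. At least 2-fold, PMEL and shFHL2 shared 15 higher and 83 lower genes (8.65 and 28.7 for independent lists) with 74 opposite (36.1), and PMEL and shNFYA shared 10 and 86 (9.87 and 32.7) with 75 opposite (41.2). The simulated unchanged groups shared no called gene in any of 20 simulations. They held no changed genes, so this cannot show how much the shared GFP arrays add to the observed overlaps. ARHGAP20, CPED1, ZNF385B, OLFML3 and NPTX1 fell by over 3 log2 in all 3 comparisons, and MGST1 rose in all 3; with values under log2 4 set to 4, ARHGAP20 was at -2.92 and CPED1 at -2.82 in each. FOS and FOXD3 rose 2.86-fold and 2.82-fold with PMEL and 4-fold and 3.05-fold with shFHL2, and IL24 rose with PMEL by 1.29 and with shNFYA by 5.89. KIAA1958 rose with PMEL (1.48, or 0.67 with that floor) and shFHL2 (1.62, or 0.81), and ANKRD36B (1.29 and 1.90) and CCDC163 (1.23 and 2.94) rose with PMEL and shNFYA. CYP2E1 was higher in all 3, from 2.48 to at most 4.34, and its call was lost in the shFHL2 and PMEL comparisons with values under log2 4 set to 4 (0.13, adjusted p = 0.398, and 0.24, adjusted p = 0.182).

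The direct comparison of A375M2 shFHL2 with shNFYA, added after the data were seen because both arms lie in the same array set, called 7672 genes, 3477 higher and 4195 lower in shFHL2. FHL2 was lower by 3.93 log2 in shFHL2 (SE 0.144, limma adjusted p = 1.32e-13), NFYA higher by 1.33, and PMEL not different by the test (0.10, adjusted p = 0.499). PMEL stood at 3.35 in shFHL2 and 3.25 in shNFYA, near the lowest values, so a difference between these arms could hardly show. TMEM132D-AS1 was higher in shFHL2 by 5.92, ENPP2 by 5.60, the cancer-testis gene PAGE1 by 5.49 and FABP7 by 4.99. CD24 was lower by 7.96 log2 in shFHL2 (SE 0.14, limma adjusted p = 1.13e-17), and FDCSP (-7.46), neurotensin (NTS, -7.11) and DRAIC (-5.64) were lower too. The other large differences were CSTA at 4.54, SLFN11 at 4.40, SPRY1 at 4.31, MCTP2 at 4.27, MPPED2 at -4.93, SULT1B1 at -4.53, SCEL at -4.43 and SPANXB1 at -4.22; with values under log2 4 set to 4, MPPED2 was at -3.14 and SCEL at -2.63. At least 2-fold, 697 genes were higher and 440 lower.

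Between these arms, G2/M genes were higher in shFHL2 at 26 and lower at 3 of 31 (camera adjusted p = 2.22e-06), with KIF20A at 2.60, DLGAP5 at 1.69, ANLN at 1.38 and TOP2A at 1.35. NF-kB and cytokine genes were lower in shFHL2 at 16 of 17 (camera adjusted p = 6.32e-06), with CCL20 at -3.48, IL1B at -3.30, PTGS2 at -2.25 and CXCL1 at -2.09. G1/S genes were higher at 19 and lower at 1 of 25 (camera adjusted p = 1.85e-05; adjusted p = 0.0873 with an estimated correlation), with UHRF1 at 2.36. MHC genes were higher at 15 and lower at 1 of 18 (camera adjusted p = 0.00011; adjusted p = 0.0873 with an estimated correlation), with HLA-DMB at 1.28 and HLA-DPB1 at 1.07. YAP and TEAD targets were higher at 10 and lower at 2 of 15 (camera adjusted p = 0.0046; adjusted p = 0.0956 with an estimated correlation), with CRIM1 at 1.39 and CCN2 at 1.23. Pigmentation genes were higher at 9 and lower at 3 of 18 (camera adjusted p = 0.0272; adjusted p = 0.0873 with an estimated correlation), with PAX3 at 1.71 and RAB27A at 1.40. Undifferentiated genes were higher at 11 and lower at 2 of 19 (camera adjusted p = 0.0272; adjusted p = 0.0956 with an estimated correlation), with COL13A1 at 2.01. The epithelial-mesenchymal list was higher at 12 and lower at 4 of 20 (camera adjusted p = 0.033; adjusted p = 0.0873 with an estimated correlation), with SNAI2 2.29-fold and TWIST1 1.77-fold higher. Extracellular matrix genes were higher at 11 and lower at 3 of 21 (camera adjusted p = 0.0329; adjusted p = 0.121 with an estimated correlation), with FBN1 at 2.19. Adjusted over the list alone, 20 G1/S genes were higher and 3 lower and 16 MHC genes higher, and the other 7 called lists kept their counts.

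This comparison and the C32 comparison called 2342 genes the same way, 1138 higher and 1204 lower (1167 and 1131 with each array centred), against 1120 and 1270 for independent lists, and 2620 in opposite directions, against 2410 (r across genes -0.03). At least 2-fold in both, 46 genes were higher and 29 lower, where independent lists would share 24.5 and 22.2, and 98 went in opposite directions, against 50.6. FAM133A (2.60 and 4.11 log2), TLR4 (1.80 and 6.10), CRYBG1 (2.08 and 1.63) and S100A3 (1.62 and 1.76) were higher in shFHL2 than in shNFYA and rose in C32. PLSCR4 (4.66-fold and 3.99-fold), ADCY1 and FHL2 were lower in shFHL2 than in shNFYA and fell in C32. A difference between the A375M2 arms can come from either shRNA. ADCY1 stood at 2.45 in A375M2 shFHL2, and with values under log2 4 set to 4 its difference between the A375M2 arms was -0.45. COL8A1, MUC7 and TCN1 were also called in both, but with values under log2 4 set to 4 the calls of COL8A1 and MUC7 were lost between the A375M2 arms (0.03 and -0.14) and that of TCN1 in C32 (0).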

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

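The shared-effect, C32-cell and culture-history tests of the first pattern and the tests of the RAP1A and replicate 3 patterns were chosen only after the result was seen; the offset and copy-number tests and the splits of the arrays for the planned comparisons were not, while the split for shFHL2 against shNFYA belongs to a comparison added after the data were seen.

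The effect of the FHL2 shRNAs differed between C32 and A375M2 by the interaction test at 8772 genes, and the named genes and lists here are those whose effect differed. The median difference, C32 minus A375M2, was 2.02 for G2/M and mitosis, -1.60 for the unfolded protein response, -1.77 for NF-kB and inflammatory cytokines and -1.07 for interferon response (camera adjusted p = 0.00304; adjusted p = 0.119 with an estimated correlation). FHL2 differed by -1.21 (limma adjusted p = 6.21e-05), PMEL by -1.32 (5.08e-06) and NFYA by 0.61 (0.000733). PMEL went from 5.57 to 3.35 in A375M2, under log2 4, and from 7.61 to 4.08 in C32. Its fall in A375M2 may be limited by the lowest values, so the PMEL responses of the lines cannot be ranked. HGF differed by 10.46, SPATS1 by 9.74, SOX9 by 8.78, ARMCX2 by 8.41 and TXNIP by 8.28. CNTN4 differed by -10.47, AXL by -9.51, SERPINH1 by -9.09, COL6A3 by -9.08 and LCN2 by -8.94. HGF, COL6A3 and LCN2 were at the lowest values in the C32 GFP and C32 shFHL2 arrays, so that their differences are those of A375M2 alone. The A375M2 changes in this contrast cross array sets and were largely shared with shNFYA (r = 0.896 across genes), where FHL2 was not called different. HGF, SOX9, ARMCX2, SPATS1, SERPINH1 and COL6A3 changed the same way by a similar amount in A375M2 shNFYA. Their differences between the lines are therefore not particular to the FHL2 shRNAs.

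The first pattern is that the A375M2 shFHL2 and shNFYA arrays differed together from the A375M2 GFP arrays. Against offsets of single probe sets from separate array processing as the only source, the shFHL2 changes of the 2 brightest probe sets of a gene went together (r = 0.722 across genes), as they did in C32 (0.739) and between the shRNA arms (0.717). Offsets on top of shared changes would still leave such a correlation, so they cannot be excluded as a part of the pattern. At 186 probe sets with exact low values, the A375M2 shRNA arms lay -0.57 log2 (SD 0.955) from replicates 1 and 2 of A375M2 GFP and PMEL. The shared-effect test asked whether the shRNA vector and its selection acted alike in both lines. It took 189 genes over 8-fold different in both A375M2 shRNA arms and at log2 6 or more in a C32 group. Their median C32 change was 0.203 (bootstrap interval 0.0857 to 0.308) where A375M2 had 4.1, which argues against such an effect for the set. Of them, 35 were called at least 1 log2 different the same way in C32 and 13 the opposite way. Genes already high in C32 GFP had less room to rise. FHL2 was not called different in shNFYA (-0.11), so genes picked in both arms cannot test FHL2 loss. Against C32 cells among the A375M2 shRNA cells, 58 genes at least 64-fold higher in C32 had a median change of -0.00911 (-0.125 to 0.306), 39 of them under log2 4 in shFHL2. A different copy number cannot be told apart, since windows of neighbouring genes spread 2.26 times as widely as in shuffled order, which met the bound set beforehand over PMEL at 2.24, but all comparisons gave 1.72 to 2.57 with a spread of 0.138 between shuffles. A different A375 population or culture history and a response of A375M2 alone stay open and cannot be told apart from the array set; that 80.3 percent of genes over 2-fold different in shFHL2 were so the same way in shNFYA restates the pattern and favours neither.

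After the first run, the shared-effect test was limited to genes at log2 6 or more in a C32 group, and in it and the C32-cell test an interval of the median replaced a condition on the quartiles. By that condition the C32-cell test, with an upper quartile of 1.76, would have decided nothing. The margin over the shuffle spread in the copy-number test was also added afterwards.

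The next pattern is that a pair of RAP1A probe sets was bright in every GFP and PMEL array and at 2.40 and 2.43 in the shRNA groups, with a gap of 10.7 log2 between the dimmest array of the former and the brightest of the latter. Against a change of RAP1A mRNA in C32, the larger C32 change of the other RAP1A probe sets was 0.33 log2 (limma adjusted p = 0.0903). In A375M2 a change of RAP1A mRNA stays open, since the other probe sets went apart, the one changing by -2.73 in shFHL2 and -3.49 in shNFYA (7.14e-12 and 1.72e-13) and the other by 0.74 and 0.45 (1.8e-09 and 1.18e-06). Sequence shared with the CMV-IRES vector may be the source, but no vector sequence was at hand and the labels do not say which GFP vector was used, so it cannot be told apart from other differences between the groups with and without shRNAs.

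The last pattern is that replicate 3 of A375M2 GFP, A375M2 PMEL and C32 GFP did not vary freely; each of the A375M2 arrays shared 222 equal values with that of C32. Over 16775 probe sets, the deviations of A375M2 GFP and PMEL replicate 3 from the means of replicates 1 and 2 cancelled, with an SD of 0.00644 for their sum against 0.114 for each (r = -0.998), which is consistent with an adjustment for a batch of these arrays within each line. Against a copy of another array, the closest array to A375M2 GFP replicate 3 lay at an SD of 0.141. No biological explanation was tested. If that adjustment was made, the spread between these arrays may be too small. The comparisons share an estimate of the spread, so p-values may be too low in all of them, not only against A375M2 GFP.

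In the splits of 6 arrays into groups of 3, the real split gave 9323 called genes for A375M2 shFHL2 against GFP (highest of the other splits 0), 3878 for PMEL (1), 9359 for shNFYA (0) and 7358 for shFHL2 against shNFYA (0). In each, 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.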

How the results depend on the processing

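The reported fit on 17 arrays, in place of the planned one on 18, the comparison of shFHL2 with shNFYA, and the tests on replicate 3 of A375M2 GFP and PMEL were chosen only after the result was seen. Counts of called genes, overlaps and lists other than those given here stayed within 1.5 times the reported one. Leaving out 1 array in turn gave 9113 to 9189 genes for A375M2 shFHL2, 3700 to 4078 for PMEL, 9299 to 9383 for shNFYA, 6233 to 6580 for C32 shFHL2, 9077 to 9298 between the lines, 8532 to 8709 for the interaction and 7297 to 7456 for shFHL2 against shNFYA, and 3096 to 3364 shared by the shFHL2 comparisons of both lines; where this left C32 GFP with 1 array, that array is assumed to vary like the other groups. In the same order, requiring a 2-fold change as well left 3431, 234, 3918, 936, 4715, 3715 and 1137 genes, a stricter threshold by construction. Overlaps at 2-fold were 280 for the shFHL2 comparisons of both lines, 98 for shFHL2 and PMEL, 2755 for shFHL2 and shNFYA, 96 for PMEL and shNFYA, and 75 for shFHL2 against shNFYA and C32 shFHL2. With an estimated correlation, lists called fell from 6 to 3 for A375M2 shFHL2, from 5 to 0 for PMEL and from 9 to 2 for shFHL2 against shNFYA; fry, which does not compare a list with other genes, called 23, 20, 25, 24, 25, 23 and 24. Under the stricter filter, 174 list results did not change, 1 gained a call and 7, those of the keratinocyte markers, could not be run with the members left. The planned fit on all 18 arrays gave 9408, 4649, 9566, 7374, 9575, 8988 and 7817 genes. For PMEL, a batch term for replicate 3 of GFP and PMEL gave 4105 genes and leaving both arrays out 3250. Same-numbered arrays did not pair: over 40 pairs the median r was -0.0112 with 0 above 0.1, and 2 of 17 arrays were closest to their own number; the replicate block gave 9280, 4191, 9461, 6666, 9318, 8662 and 7564 genes. Centring each array moved the median of all shNFYA changes from 0.0017 to 0.11, and turned the balance of higher and lower genes to 4943 and 4413 for A375M2 shFHL2, 2045 and 2142 for PMEL, and 4336 and 4441 for the interaction; the balance of 4 of the 5 overlaps turned as well, all but that of PMEL and shNFYA. Of 7526 values of 376 named gene results under the alternatives, 7512 kept their call, 5 gained it, 9 lost it and 0 reversed. FHL2 gained a call with only the arrays compared, in PMEL (-0.20, adjusted p = 0.0171), shNFYA (-0.11, 0.0273) and between the lines (-0.13, 0.0463), and NFYA gained it between the lines with the mean over probe sets and with the probe set of largest variance. Signal near the lowest values limits folds: 6 of the 9 lost calls came with values under log2 4 set to 4. Causes were not tested otherwise.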

Other observations

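The test of neighbouring genes was chosen only after the result was seen.

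Of the 5 measured NF-Y subunits and partners, POLE3 (1.37), NFYC (1.03) and NFYB (0.62) rose and NFYA (-2.07) and CHRAC1 (-0.28) fell in A375M2 shNFYA, and the list was not called (camera adjusted p = 0.586).

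Genes silent in C32 GFP and expressed in A375M2 GFP may lie in segments deleted in C32; this is a hypothesis from the values themselves. Neighbours were taken among the 10910 genes tested and placed on chromosomes, so genes that were not measured may lie between them. Of 154 such genes, 10 pairs were neighbours in that order, against a mean of 2.13 and a highest count of 9 in 10000 shuffled gene orders. The 59 genes of the reverse set gave 0 pairs, where shuffled orders gave a mean of 0.313, so that count cannot separate the explanations. MINPP1, PAPSS2 and ATAD1, chosen after their values were seen, lie next to each other and stood at 11.85, 12.98 and 12.72 in A375M2 GFP against 2.22, 2.21 and 2.38 in C32 GFP. The other pairs were CHRM3 and FMN2, CNTN3 and LINC00960, TRPC1 and PCOLCE2, STC1 and NEFL, CLMP and GRAMD1B, FERMT1 and BMP2, LDOC1 and MAGEC2, and MAGEA4 and MAGEA10. Neighbouring genes that are regulated together could give such pairs as well, and no copy number was measured.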
